A study of Mus musculus with 6 samples.

How the data were processed

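The series holds 6 single-cell RNA libraries of mouse brain cells, made with droplet 3' kits and sequenced in paired-end mode per the labels. There are 2 libraries each of wild type with vehicle (WT vehicle), wild type with bilirubin (WT bilirubin), and TRPM2 Mg KO with bilirubin. Nothing in the labels says that the replicates came from separate animals, so p-values here measure the spread between these libraries, which may be technical. The title of the series names a role of the liver under stress in negative emotions. Dose, duration, brain region, age and sex of the animals were not given in the sources used here.

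The authors deposited, per library, a matrix of UMI counts with its barcodes and genes. The values are deposited counts, whole numbers of UMIs per gene and cell, with no normalization. The barcode and gene tables are deposited names, an other kind of content that holds no measurement. The submitters' processing notes list Cell Ranger 8.0.0 and Scanpy 1.9.6, and the builds GRCm39 and mm10 without a role; the matrix headers name Cell Ranger 9.0.1 in all 6 libraries. How cells were called is not given in the sources used here. The build behind the counts is unclear, so no coordinates are printed. All 6 gene tables hold the same 33696 genes.

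The libraries held 4137 to 24309 barcodes and 24165563 to 63402551 UMIs, with a median of 1149 to 2071 UMIs per barcode. Cells with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs were kept. Doublets were called per library with Scrublet in scanpy 1.11.5 and removed, 10453 in all. In knockout replicate 2 its automatic threshold called none, and the 3.31% of cells with the highest scores, the expected rate, were removed instead. In all 83691 of 95014 barcodes stayed.

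Counts were scaled to 10000 per cell and log-transformed, and 3000 variable genes were chosen, of which 2986 were used. The 40 first principal components and 15 neighbours gave 28 Leiden clusters at resolution 1, over all libraries together and with no batch correction. A cluster got a class name, written as "-like", only from markers fixed before the data were seen: at least 3 markers and 40% of the list set it apart, and at least 1.5 times as many as for the next class. These thresholds were set after seeing the data. The rule named 18 clusters and 14 classes, and left 10 clusters with 50.8% of the kept cells unnamed. A marker counted only where at least 10% of the cluster's cells held it. The names are rebuilt here and need not match those of the study.

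UMIs were summed per library and class (pseudobulk). The 10 classes with at least 20 cells in each library were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM normalization and filterByExpr. All 6 libraries were in 1 fit with group as the only term and 3 residual degrees of freedom, since an exact permutation test of 2 against 2 libraries cannot pass. P-values were adjusted by Benjamini and Hochberg per class and comparison, with a threshold of 0.05. The comparisons were WT bilirubin against WT vehicle, the knockout with bilirubin against WT bilirubin, and the knockout with bilirubin against WT vehicle. CPM in a class are scaled by the TMM factors, those of whole libraries are not. Standard errors come from the fold change and the test statistic.

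The 29 gene lists fixed before the data were seen were tested with camera from limma 3.58.1 with a preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry. Shares of cells were tested with edgeR on cell numbers, with kept cells as library size. For shares of cells with a UMI, the chance of at least 1 UMI after thinning to 1000 UMIs was averaged over the cells that were deep enough. A group's count of 0 was set to 3 counts to give a fold; floors and intervals cover counting error only.

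Genes were named by a rule written before the data were seen. In microglia-like cells these were the 8 highest and 8 lowest log2 fold changes among called genes with a mean CPM of at least 5 and no overlap between the libraries of both groups, filled up to 16 by the smallest p. The 2 members of each list with the smallest p, Trpm2, and the 3 highest and 3 lowest in each other class by the same criteria were added. Predicted genes, ribosomal proteins, mitochondrially encoded genes and haemoglobins were counted but not named by size. Values of named genes outside the comparison that named them, such as Cebpb in neutrophil-like cells, were added after they were seen.

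The tests were tested on simulated data. In microglia-like cells, 4-fold changes were found for 72.7% of genes in the bilirubin comparison and 67% in the knockout comparison, and 2-fold changes for 5% and 3%. In endothelial-like cells, 4-fold changes were found for 88.5% and 88.8%. For each fold 100 genes were changed, and those that filterByExpr removed were left out of these percentages. A list changed 2-fold was called in both comparisons with the preset correlation (adjusted p = 5.49e-17 and 6.71e-14) and in neither with an estimated one (0.0737 and 0.099). So 2-fold changes in single genes were mostly missed, folds between 2 and 4 were not simulated, and the estimated correlation missed the list that was moved. Genes were simulated independently of each other. The simulation therefore cannot show whether the preset correlation calls too many lists in libraries where genes move together.

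The alternatives tried were DESeq2 1.42.0, median-of-ratios size factors, no low-count filter, a replicate block, only the 4 libraries compared, each library left out in turn, a stricter cell filter (1000 UMIs, 10% mitochondrial), doublets kept, Leiden resolution 2, equal cell numbers, TMM factors over classes for the shares, and a mean CPM of at least 20 for the correlation across genes. Added after the data were seen were a term for libraries with a median mitochondrial percentage of 2 or more (which leaves 1 WT bilirubin library, a different one, in each comparison with that group), only genes above their whole-library level, the largest cluster of each class alone, and a crossed pairing. When an arm keeps 1 library, that library is assumed to vary like the others. Velocity, splicing and reads were not analysed here.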

Results

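Trpm2, the gene that the knockout label names, was counted in every library. In microglia-like cells it had 89 and 102 UMIs in the WT vehicle libraries, 118 and 80 in the WT bilirubin libraries, and 72 and 23 in the TRPM2 Mg KO bilirubin libraries. These counts came to 23.2 and 14.7, 19 and 38.2, and 15.8 and 19.4 CPM, UMI counts scaled to the same library total. The log2 fold change of the knockout against WT bilirubin was -0.69 (SE 0.41, n = 2 libraries per group, edgeR adjusted p = 1), and that of WT bilirubin against WT vehicle was 0.57 (SE 0.39, adjusted p = 0.536). A 3' tag outside the deleted part of a gene is counted as before, so this level neither checks nor contradicts the knockout. The labels do not expand "Mg".

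The share of microglia-like cells with a Trpm2 UMI was 3.88% ± 0.0375 (SD, n = 2) with vehicle, 8.61% ± 1.07 with bilirubin and 7.18% ± 0.279 in the knockout. The cells of these groups differed in depth, with median UMI counts of 1695 and 2700, 3787 and 2386, and 4362 and 3280 per library. After each cell was thinned to 1000 UMIs the shares were 1.79% ± 0.474, 3.05% ± 1.05 and 1.98% ± 0.214, with 342, 195 and 40 shallower cells left out. Choroid plexus-like cells, taken here as a type that should lack the gene, at median UMI counts of 2031 and 3864, 5099 and 2477, and 5420 and 3221, had thinned shares of 0.584% ± 0.49, 0.105% ± 0.029 and 0.243% ± 0.184. In the whole libraries, Trpm2 had 11.8 and 6.42, 5.12 and 8.22, and 6.61 and 4.59 CPM. Excitatory neuron-like cells of the knockout held 14.3 CPM in replicate 1 and 0 UMIs in replicate 2, which had 44 such cells.

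With bilirubin in wild-type mice, Il1b, Ccl7, Socs3 and neutrophil markers rose in microglia-like cells and neuronal transcripts fell. Socs3 is in the fixed list of immediate-early and dissociation genes, which was set as a check of quality and sample make-up. Il1b rose from 9.11 ± 4.03 to 43.5 ± 9.36 CPM (SD, n = 2; log2 fold change 2.21, SE 0.38, adjusted p = 0.0456), Ccl7 from 2.06 ± 2.18 to 22 ± 4.82 CPM (3.26, SE 0.56), and Socs3 from 71.2 ± 9.37 to 182 ± 24.7 CPM (1.36, SE 0.32). The neutrophil markers S100a8 (2.93, SE 0.41), S100a9 (2.21, SE 0.34), Lcn2 (3.73, SE 0.74) and Camp (2.23, SE 0.51) rose in the same cells, and so did Adap2os (2.84, SE 0.62) and Nectin2 (1.74, SE 0.38). S100a8 went from 6.38 to 49.8 CPM in microglia-like cells, against 64.9 to 712 CPM in the whole libraries and 13400 to 60800 CPM in neutrophil-like cells, and the log2 fold changes of S100a8, S100a9 and Lcn2 were above 0 in all 10 tested classes. The largest falls were those of the neuronal transcript Bc1 (-3.42, SE 0.66), H1f5 (-3.06, SE 0.69), C1ql3 (-2.97, SE 0.59), Dio2 (-2.75, SE 0.46), Svop (-2.63, SE 0.49), Trhde (-2.58, SE 0.47), Nefm (-2.53, SE 0.52) and Ndst3 (-2.48, SE 0.57). Bc1 alone took 7585 ± 6710 CPM with vehicle and 711 ± 121 CPM with bilirubin. The glutamate receptor genes Grin2a (-2.05, SE 0.37) and Grin2b (-1.97, SE 0.38) and the calcium channel gene Ryr3 (-1.68, SE 0.38) fell too.

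In all, 234 of 14296 genes changed, 15 higher and 219 lower. The Wald test of DESeq2 called 358, of which 218 were the same genes. Among the 7433 genes whose CPM in microglia-like cells was above that of the whole libraries, 1 gene was called. The count was 2 with median-of-ratios size factors, and it ran from 0 without a knockout library to 1454 without WT bilirubin replicate 1. Il1b, Ccl7 and Socs3 lost their calls without WT vehicle replicate 1, without either knockout library, with only the 4 libraries compared, with median-of-ratios size factors, under the stricter cell filter, in the largest cluster alone and among genes above their whole-library level. They passed in 10 of 18, 9 of 17 and 6 of 18 alternative settings, and Socs3 was lost without WT vehicle replicate 2 and without WT bilirubin replicate 2 too; the log2 fold change of Il1b stayed between 1.84 and 3.11. S100a8 passed in 13 of 17 alternative settings, S100a9 in 12 of 17, Lcn2 in 8 of 16, Camp in 6 of 17, Adap2os in 8 of 18 and Nectin2 in 7 of 18. Of the falls, Bc1, C1ql3, Dio2 and Grin2a passed in 9 of 17 settings and Nefm, Grin2b and Ryr3 in 8 of 17. Trhde passed in 9 of 16, Svop in 8 of 16, Ndst3 in 6 of 16 and H1f5 in 5 of 16. Each of these falls was lost without WT vehicle replicate 1, with median-of-ratios size factors and under the stricter cell filter. Each was also lost in the largest cluster alone and with only the 4 libraries compared. All these genes lost their calls without either knockout library.

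Cebpb was the 1 gene of 14296 that changed between knockout and wild type under bilirubin in microglia-like cells. Its level was 271 ± 5.93 CPM in WT bilirubin and 36.5 ± 9.78 CPM in the knockout (log2 fold change -2.87, SE 0.35, adjusted p = 0.0129), against 122 ± 2.9 CPM with vehicle. The gene, ENSMUSG00000056501, encodes the transcription factor C/EBP beta. The share of microglia-like cells with a Cebpb UMI after thinning was 10.8% ± 0.431 with vehicle, 23.2% ± 0.354 with bilirubin and 3.96% ± 1.18 in the knockout; before thinning it was 21.9% ± 6.19, 48.2% ± 13.2 and 15% ± 6.02. Choroid plexus-like cells had thinned shares of 2.02% ± 0.79, 2.92% ± 1.04 and 0.535% ± 0.153. The difference passed in 16 of 18 alternative settings, and missed the threshold without knockout replicate 1 (adjusted p = 0.663) and without replicate 2 (adjusted p = 1), at log2 fold changes of -3.20 and -2.63. Without WT bilirubin replicate 1 the comparison called 61 genes, 45 higher and 16 lower; without WT vehicle replicate 1 or 2 it called 6 or 7, and without either knockout library 0. With no low-count filter 13 were called, and with only the 4 libraries compared 5. The rise of Cebpb with bilirubin in these cells did not pass (log2 fold change 1.15, SE 0.32, adjusted p = 0.0837).

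**Figure D1:**
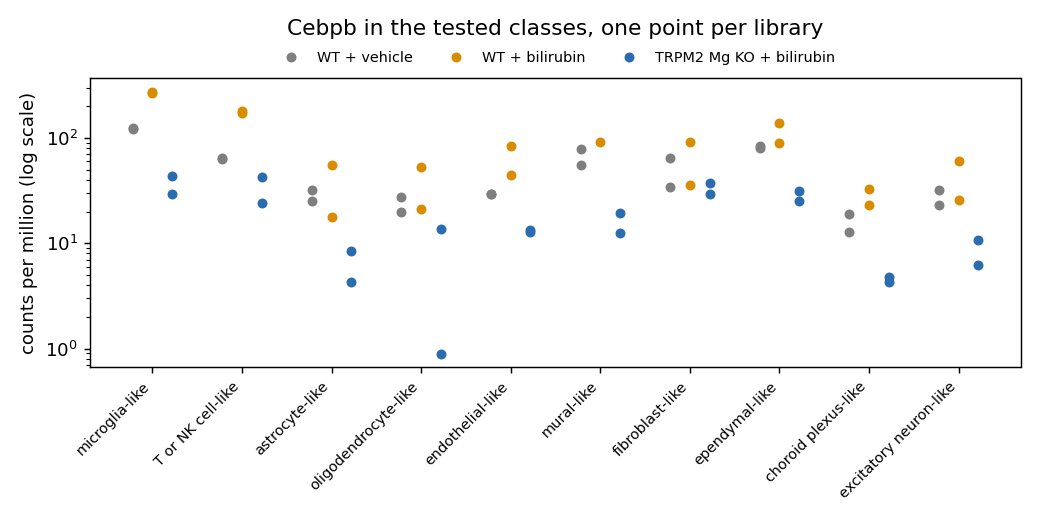
CPM of Cebpb (log scale) in the 10 tested cell classes, with 1 point per library and 2 libraries per group; a library with no count has no point. In microglia-like cells the WT bilirubin libraries lie at 275 and 267, the vehicle libraries at 120 and 124, and the knockout libraries at 43.4 and 29.6.

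Cebpb was lower in the knockout than in WT bilirubin in each of the 10 tested classes, by log2 fold changes from -3.56 to -1.39. The difference passed in microglia-like, endothelial-like (-2.38, SE 0.36, adjusted p = 0.0019) and choroid plexus-like cells (-2.61, SE 0.41, adjusted p = 0.00125). It was lost in both of the latter without knockout replicate 1, and in endothelial-like cells without WT bilirubin replicate 1 (log2 fold change -1.69). Neutrophil-like cells, with 19 and 11 cells in 2 libraries and so not tested, held 173 ± 21.2 CPM with vehicle, 1080 ± 63.6 with bilirubin and 190 ± 24 in the knockout. In the whole libraries the values were 43.6 ± 8.2, 86.7 ± 11.4 and 13.9 ± 0.636 CPM.

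The other genes with the smallest p of the knockout comparison in microglia-like cells did not pass. S100a9 had a log2 fold change of -2.20 (SE 0.35, adjusted p = 0.121), S100a8 of -2.41 (SE 0.42, adjusted p = 0.208), and Camp of -3.19 (SE 0.62, adjusted p = 0.481). For the complement gene C4b it was -2.04 (SE 0.49), for Ccl5, a T and NK cell marker, -1.88 (SE 0.47), for Cst7 -1.94 (SE 0.50), and for Ccl7 -1.94 (SE 0.55), all with an adjusted p of 1. The histone gene H4c17 had 0 counts in WT bilirubin and 23 in the knockout, 11.7-fold more when the group's 0 is set to 3 counts (lower 95% counting limit 8.75), and Clhc1 had 0 and 16 counts, 8.12-fold more (lower limit 5.87). Capn11 went the other way, with 33 counts in WT bilirubin and 1 in the knockout, a ratio of 21.7 (95% counting interval 3.63 to 882). DESeq2 called 3 genes in this comparison, all lower. At unadjusted p under 0.05 stood 247 genes.

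Between the knockout with bilirubin and WT vehicle, edgeR called 0 of 14296 genes in microglia-like cells, with 1354 at unadjusted p under 0.05 and 3 called by DESeq2. Cebpb had a log2 fold change of -1.71 (SE 0.34, adjusted p = 0.406) and Il1b of 1.44 (SE 0.40, adjusted p = 0.406). Without WT bilirubin replicate 2 the count was 230. The labels give no knockout group with vehicle, so whether the knockout alters the response to bilirubin cannot be tested as an interaction.

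The 2 comparisons that share the WT bilirubin libraries ran opposite to each other across genes in microglia-like cells. Pearson's r over 14296 genes was -0.547 and the covariance -0.176; genes are not independent replicates. Unchanged groups simulated with the same shared libraries gave r = -0.487 and a covariance of -0.12, so the shared libraries alone can give most of the relation. By itself it does not show that the knockout reverses the bilirubin response. With 1 library left out r ran from -0.8603 to -0.2729. With the mitochondrial term, where the comparisons share no library, r had the opposite sign. WT bilirubin has too few libraries to split into separate controls with replicates.

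In endothelial-like cells Scgb3a1, Lrg1 and Lcn2 rose with bilirubin. Scgb3a1 rose from 16 ± 1.18 to 456 ± 224 CPM (SD, n = 2; log2 fold change 4.81, SE 0.47, adjusted p = 4.84e-06), Lrg1 from 2.57 ± 0.334 to 61.8 ± 3.6 CPM (4.58, SE 0.62, adjusted p = 0.000421), and Lcn2 from 10.3 ± 1.34 to 172 ± 13.4 CPM (4.08, SE 0.42, adjusted p = 6.48e-06). In the knockout with bilirubin they stood at 48.5 ± 13.9, 5.83 ± 5.24 and 34.9 ± 12 CPM, lower than in WT bilirubin by log2 fold changes of -3.25 (SE 0.41, adjusted p = 0.000211), -4.04 (SE 0.48, adjusted p = 0.000153) and -2.38 (SE 0.34, adjusted p = 0.00127). All 3 rises passed in 18 of 18 alternative settings; the 3 falls passed in 17 and were lost without knockout replicate 1. With Cebpb, these 3 genes were the 4 that the knockout comparison called in endothelial-like cells. The log2 fold changes of the 3 genes were above 0 with bilirubin in all 10 tested classes. They were below 0 in the knockout comparison in all 10 too. In the whole libraries Scgb3a1, Lrg1 and Lcn2 stood at 26.6 ± 19.3, 12.7 ± 4.61 and 92 ± 18.3 CPM in WT bilirubin. In the knockout they stood at 17 ± 13.1, 7.99 ± 5.24 and 41.4 ± 29.2 CPM, a smaller fall. Unnamed cluster 25, with the endothelial marker Cldn5 among its leading genes, held 21.7% of knockout replicate 2 and entered no comparison. Whether its cells would change the falls was not tested. At Leiden resolution 2 the endothelial-like cells lay in cluster 6, with 3.64% and 1.97% of the vehicle libraries' cells and 2.79% and 1.11% of the WT bilirubin libraries' cells, and in cluster 24, led among others by Scgb3a1, with 0.12% and 0.32% against 3.55% and 0.906%. The knockout libraries held 3.29% and 7.13% in cluster 6 and 5.52% and 2% in cluster 24.

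**Figure D2:**
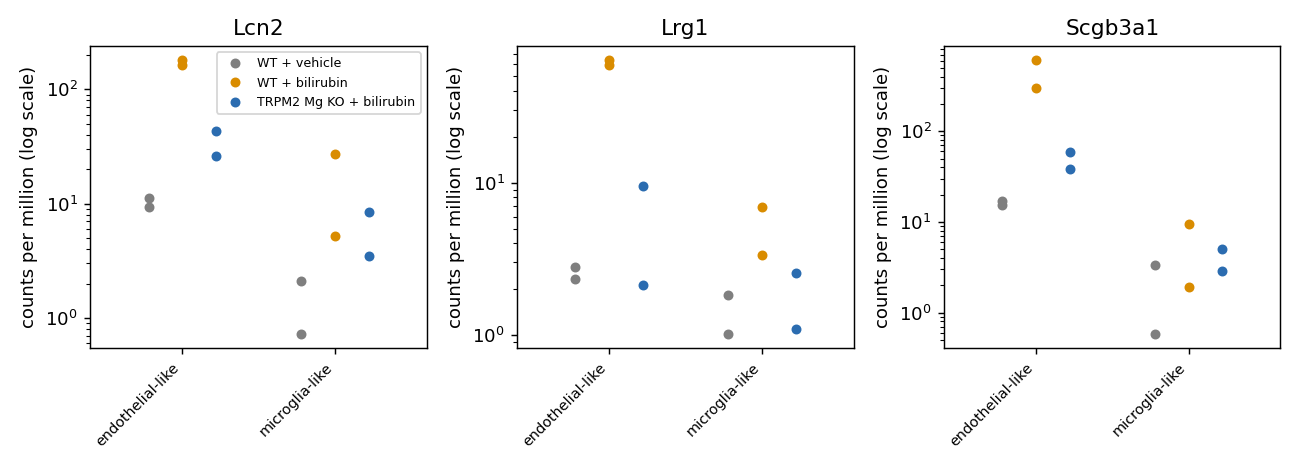
CPM (log scale) of Lcn2, Lrg1 and Scgb3a1 in endothelial-like and microglia-like cells, with 1 point per library and 2 libraries per group. In endothelial-like cells the WT bilirubin libraries lie above both other groups for each gene, as in the group means of 172, 61.8 and 456.

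In endothelial-like cells 363 of 10180 genes changed with bilirubin, 48 higher and 315 lower, against 4 in the knockout comparison, all lower. Among the 5893 genes above their whole-library level, 7 and 3 were called, with 1 of the 7 lower, and DESeq2 called 121 and 4. Without WT vehicle replicate 1 the first count was 40, and without knockout replicate 1 the second was 0. Gja4 had 0 counts with vehicle and 40 with bilirubin, 4.58-fold more when the group's 0 is set to 3 counts (lower 95% counting limit 3.56; passed in 7 of 14 alternative settings), and Slc16a1, of the blood-brain barrier list, rose (log2 fold change 1.55, SE 0.36, adjusted p = 0.0188) and passed in 12 of 18, being lost without either vehicle library, without WT bilirubin replicate 2 and without knockout replicate 1, among others. The falls were led by Bc1 (-3.57, SE 0.67), C1ql3 (-3.30, SE 0.48) and Xkr6 (-2.62, SE 0.58). The fixed list of endothelial activation held 5 genes that rose over all genes tested and 7 adjusted over the list alone, of 17 (camera adjusted p = 7.95e-08, adjusted p = 0.236 with an estimated correlation). In the knockout comparison 2 of its genes fell over all genes tested and 6 adjusted over the list alone, Lcn2, Ackr1, Vwf, Lrg1, Ch25h and Il1r1 (adjusted p = 1.04e-14, adjusted p = 0.127 with an estimated correlation). The blood-brain barrier list rose with bilirubin (adjusted p = 5.34e-06, adjusted p = 0.437 with an estimated correlation), with 1 gene over all genes tested and 2 adjusted over the list alone.

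In the other tested classes bilirubin called 425 genes in choroid plexus-like cells, 201 in oligodendrocyte-like, 36 in ependymal-like, 30 in fibroblast-like, 8 in excitatory neuron-like, and 3 each in astrocyte-like and mural-like cells. In the same order DESeq2 called 217, 77, 9, 2, 2, 16 and 0, and among genes above their whole-library level 1, 0, 0, 14, 2, 0 and 3 were called. T or NK cell-like cells had 0 by edgeR, with 713 at unadjusted p under 0.05 and 3 by DESeq2. The neutrophil marker S100a8 rose by 3.57 (SE 0.45) in choroid plexus-like, 3.86 (SE 0.66) in ependymal-like, 3.10 (SE 0.42) in excitatory neuron-like and 2.06 (SE 0.42) in oligodendrocyte-like cells, and S100a9 by 2.07 (SE 0.38) in astrocyte-like and 2.59 (SE 0.44) in ependymal-like cells, all in log2. With bilirubin S100a8 stood at 33.8 CPM in choroid plexus-like, 58 in ependymal-like and 91.5 in excitatory neuron-like cells, against 712 CPM in the whole libraries. Lcn2 rose in choroid plexus-like (3.36, SE 0.66) and excitatory neuron-like cells (3.89, SE 0.63), and Scgb3a1 in the latter (3.93, SE 0.70). With bilirubin Lcn2 stood at 10.5 ± 9.09 and 37 ± 41.8 CPM in these classes, against 92 in the whole libraries, and Scgb3a1 at 18.1 ± 14 CPM, against 26.6 in the whole libraries and 456 in endothelial-like cells. Clec3b rose in fibroblast-like (3.56, SE 0.64), choroid plexus-like (3.09, SE 0.65) and ependymal-like cells (2.18, SE 0.45). Bc1 fell in mural-like (-2.85, SE 0.62), choroid plexus-like (-2.85, SE 0.45) and fibroblast-like cells (-3.01, SE 0.60), and Dio2 in excitatory neuron-like cells (-2.45, SE 0.44). Bc1 passed in 10 of 18 alternative settings in mural-like cells, where DESeq2 did not call it, and in 16 of 18 in fibroblast-like cells; in choroid plexus-like cells it was lost in the largest cluster alone. In excitatory neuron-like cells Lcn2 and Scgb3a1 passed in 10 of 16 and Dio2 in 12 of 17, and in astrocyte-like cells S100a9 passed in 10 of 17. Lcn2 passed in 12 of 16 in choroid plexus-like cells and Clec3b in 13 of 18 in ependymal-like cells.

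Other genes named in these classes follow, with no test of a difference from the other classes. In fibroblast-like cells Ptgds (2.95, SE 0.71) and Ppp1r1b (2.57, SE 0.52) rose, and Basp1 (-2.20, SE 0.58) and Cck (-2.14, SE 0.56) fell. In ependymal-like cells Epha6 (-3.34, SE 0.50) and Khdrbs2 (-2.99, SE 0.66) fell. In oligodendrocyte-like cells Aldh3b1 (2.52, SE 0.57), Slc16a8 (2.50, SE 0.63) and Mog (1.23, SE 0.31) rose and Sgcz fell (-3.49, SE 0.48); Nrip3 had 31 counts with vehicle and 1 with bilirubin, a ratio of 30.8 (95% counting interval 5.14 to 1260), and Nell1 24 and 2, a ratio of 11.9 (2.96 to 104). Of these, Sgcz passed in 15 of 16 alternative settings, Nrip3 in 9 of 15, Aldh3b1 in 8 of 17, Slc16a8 in 5 of 16, Mog in 5 of 18 and Nell1 in 3 of 15. In fibroblast-like cells Ptgds passed in 13 of 18, Ppp1r1b in 12 of 16, and Basp1 and Cck in 8 of 17; in ependymal-like cells Epha6 passed in 15 of 17 and Khdrbs2 in 8 of 16. The myelin list rose in these cells (adjusted p = 2.62e-07, adjusted p = 0.623 with an estimated correlation), with 1 gene over all genes tested and 7 adjusted over the list alone. The reactive astrocyte list was not called in astrocyte-like cells (adjusted p = 0.925), where Gfap had a log2 fold change of 0.72 (SE 0.40, adjusted p = 0.684).

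The knockout comparison called 7 genes in choroid plexus-like, 4 in fibroblast-like, 2 in excitatory neuron-like and 1 in ependymal-like cells. Without WT bilirubin replicate 1 these counts were 120, 41, 143 and 47, and the calls over all classes other than microglia-like cells went from 18 to 461. S100a8 fell in choroid plexus-like (-2.69, SE 0.42, adjusted p = 0.0012) and excitatory neuron-like cells (-2.59, SE 0.50, adjusted p = 0.0409), and S100a9 in ependymal-like cells (-2.56, SE 0.43, adjusted p = 0.0439). In the whole libraries S100a8 went from 712 CPM in WT bilirubin to 144 in the knockout and S100a9 from 1610 to 370, and both had log2 fold changes below 0 in all 10 tested classes. The call of S100a8 was lost in choroid plexus-like cells in the largest cluster alone (adjusted p = 0.38), and passed in 9 of 16 alternative settings in excitatory neuron-like cells; that of S100a9 passed in 11 of 17. Tmsb15b1 fell in choroid plexus-like cells (-2.56, SE 0.46) and passed in 15 of 18 alternative settings. It was lost without knockout replicate 1, with an equal number of cells and in the largest cluster alone. In fibroblast-like cells Ptgds (-2.94, SE 0.71) and S100a6 (-2.08, SE 0.45) fell and H1f4 rose (2.57, SE 0.62), in 11 of 18, 9 of 18 and 7 of 16 alternative settings. Astrocyte-like, oligodendrocyte-like, mural-like and T or NK cell-like cells had 0 calls by edgeR and 0 by DESeq2, with 377, 497, 101 and 202 genes at unadjusted p under 0.05 and 3, 45, 6 and 42 calls without WT bilirubin replicate 1.

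Of 29 fixed lists, camera called 15 in microglia-like cells for bilirubin, 10 higher and 5 lower, and 11 for the knockout comparison, 4 higher and 7 lower; 0 were called in either with an estimated correlation or by fry. With the mitochondrial term 3 lists were called for the knockout, and without WT bilirubin replicate 2 there were 4, all lower, and in both fits WT bilirubin replicate 1 alone is compared with the knockout; of the 11 lists, only those of disease-associated microglia and of immediate-early and dissociation genes were among them in both. Inflammatory cytokines and NF-kB targets were higher with bilirubin (adjusted p = 0.000177, adjusted p = 0.552 with an estimated correlation), with 1 gene over all genes tested and 4 adjusted over the list alone. They were lower in the knockout (adjusted p = 5.17e-06, adjusted p = 0.583 with an estimated correlation), with 0 genes over all genes tested and 1 adjusted over the list alone. Antigen presentation moved likewise (adjusted p = 0.000926, 0.541 with an estimated correlation, for bilirubin; adjusted p = 0.000763, 0.371 with an estimated correlation, for the knockout), and so did phagocytosis and complement (0.000927 and 0.552; 0.00773 and 0.633) and lysosome and autophagy (0.000177 and 0.552; 0.00773 and 0.638).

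The homeostatic microglia list was higher with bilirubin (adjusted p = 0.00472, adjusted p = 0.552 with an estimated correlation) and not called in the knockout comparison (adjusted p = 0.444). The disease-associated microglia list was not called with bilirubin (adjusted p = 0.0552), with 3 genes higher adjusted over the list alone, and was lower in the knockout (adjusted p = 0.000379, adjusted p = 0.371 with an estimated correlation). The inflammasome list was higher with bilirubin (adjusted p = 0.00493, adjusted p = 0.552 with an estimated correlation). The synaptic and neuronal list was lower with bilirubin (median log2 fold change -1.71, adjusted p = 8.73e-21, adjusted p = 0.552 with an estimated correlation), with 9 of 19 genes lower over all genes tested and 19 adjusted over the list alone. In the knockout comparison it was higher (0.52, adjusted p = 1.71e-08, adjusted p = 0.583 with an estimated correlation), with 0 genes by either count. Haemoglobin genes were lower with bilirubin (median log2 fold change -2.09, adjusted p = 0.0264, adjusted p = 0.552 with an estimated correlation).

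The libraries split by mitochondrial percentage, and only the WT bilirubin group lay on both sides of the split. Both vehicle libraries lay under it and both knockout libraries above it. The split cannot be told apart from the group in the knockout against vehicle. The median over kept cells was 1.05% and 0.846% in the vehicle libraries, 7.23% and 0.655% in the WT bilirubin libraries, and 5.54% and 3.8% in the knockout libraries. The list of mitochondrially encoded genes was higher in microglia-like cells with bilirubin (adjusted p = 0.00262, adjusted p = 0.552 with an estimated correlation) and in the knockout (adjusted p = 1.11e-08, adjusted p = 0.583 with an estimated correlation). It turned lower without WT bilirubin replicate 1 in the first comparison and without WT bilirubin replicate 2 in the second. In the reactive astrocyte, endothelial activation, antioxidant and haem response, and blood-brain barrier lists in microglia-like cells, the median and the mean log2 fold change with bilirubin had opposite signs (-0.09 and 0.22; -0.0011 and 0.33; 0.04 and -0.01; 0.02 and -0.05), and none of them was called. In the knockout comparison this held for the unfolded protein response (0.02 and -0.0076), cholesterol efflux (-0.04 and 0.02) and endothelial activation lists (0.07 and -0.12), none of them called.

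The share of cells passed the test in no class. Of 14 named classes, 0 passed in either comparison by edgeR, and 0 and 1 stood at unadjusted p under 0.05; every alternative setting gave 0 as well. At Leiden resolution 1, microglia-like cells made up 12% ± 0.62 of kept cells with vehicle (SD, n = 2), 8.86% ± 2.1 with bilirubin and 7.17% ± 0.999 in the knockout. The order of the groups depends on the resolution. At resolution 2, microglia-like cluster 19 alone held 11.6% and 6.06% of the knockout libraries. Endothelial-like cells made up 2.75% ± 0.88, 4.54% ± 3.28 and 9.25% ± 0.0763, and T or NK cell-like cells 1.43% ± 0.4, 3.56% ± 2.99 and 0.77% ± 0.185 (knockout against WT bilirubin log2 fold change -2.21, SE 0.83, adjusted p = 0.366). In simulated data a 4-fold change of 1 class was found in 6 of 20 runs for the bilirubin comparison, so smaller shifts were mostly out of reach with these libraries. Cells with fewer than 500 UMIs had been removed, and dissociation can set such shares.

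Different clusters held some classes in different libraries. Choroid plexus-like cells lay mostly in cluster 6 in the vehicle and knockout libraries, in cluster 26 in WT bilirubin replicate 1 (15.5% of its cells), and in cluster 27 in WT bilirubin replicate 2 (41.2%). Microglia-like cells lay in clusters 4 and 11, both led by the immune and stress genes Ccl4, Ccl2, Ccl3 and Tnf beside Cx3cr1, with Il1a and Cd83 in the former and Atf3 in the latter. Cluster 11 held 1.36% and 1.92% of cells with vehicle and at most 0.532% in the other libraries. At Leiden resolution 2 the groups lay in different microglia-like clusters: cluster 5 held 11% and 6.55% of cells with vehicle against 0.116% and 0.051% in WT bilirubin. Cluster 11 held 5.2% of WT bilirubin replicate 1 and 4.71% and 3.53% of the knockout libraries, against 0.033% and 0.554% with vehicle. Cluster 19 held 11.6% and 6.06% of the knockout libraries and at most 0.568% of any other library. In knockout replicate 1 it exceeds the whole class at resolution 1 (6.47%), so part of it lay outside that class. Clusters 37 and 38 held 9.2% and 6.38% of WT bilirubin replicate 2 and at most 0.275% of any other library. In cluster 4 alone, 3 genes were called with bilirubin and Cebpb was again the 1 called in the knockout. The 10 clusters that met no naming rule held 59.8% and 51.2% of cells with vehicle, 53.3% and 10.4% with bilirubin, and 54.8% and 60.1% in the knockout. Among them, cluster 0, led by Bc1, C1ql3, Cck and Slc17a7, held 51.6% and 10.7% of the vehicle libraries, 0.311% and 0.115% of WT bilirubin, and 1.09% and 2.93% of the knockout; cluster 2, with haemoglobin genes among its leading genes, held 23.6% of WT vehicle replicate 2 and at most 2.13% of any other library. Cluster 3, led by mt-Atp8 and Lars2, held 45.6% and 20.7% of the knockout libraries, against 1.49% and 8.4% with vehicle and 1.06% and 1.29% in WT bilirubin. Bc1 and C1ql3 are among the genes that fell in named classes. The thresholds of the naming rule were set after the data were seen.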

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

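All tests in this part were chosen only after the results were seen. With the term for the mitochondrial split, the bilirubin comparison rests on WT bilirubin replicate 2 alone and the knockout comparison on replicate 1 alone, since the split parts these 2 libraries.

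The response to bilirubin differed between endothelial-like and microglia-like cells for 39 of 14395 genes, by a test of the difference itself. The bilirubin effect was higher in endothelial-like cells by a log2 of 1.405 (SE 0.21) for Ier3 and 2.656 (SE 0.40) for Sema6a, and lower by -1.498 (SE 0.22) for Zeb2, the 3 genes with the smallest p. Whether a fall of free RNA from other cells gives part of these differences was not tested. The count ran from 0 without WT vehicle replicate 1 to 475 without WT bilirubin replicate 1. For the knockout comparison the same test called 0 genes, with 425 at unadjusted p under 0.05. Scgb3a1, Lrg1 and Lcn2, named above in endothelial-like cells, were called by this test in neither comparison.

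A pair of clusters without a name, whose cells entered no gene comparison, came mostly from 1 library each, where they lay above their level in the vehicle libraries. Cluster 15, led by mt-Cytb, S100a5, Tagln and Acta2, held 44.644% of the cells of WT bilirubin replicate 1, against 0.179% in replicate 2 and 0.126% and 0.411% with vehicle. In the knockout libraries it held 2.07% and 6.55%, above vehicle too. The cells of cluster 15 had a median mitochondrial percentage of 9.838 and a median of 0.67 times their library's median UMIs. Cluster 25, with Cldn5 and Slc38a5 among its leading genes, held 21.691% of the cells of knockout replicate 2, against 0.051% in replicate 1 and 0.016% and 0.043% with vehicle, at a median of 15384 UMIs per cell. Knockout replicate 2 is the library where the automatic doublet threshold called none. Whether the barcodes of either cluster are intact single cells was not tested.

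Neuronal transcripts were lower in microglia-like cells with bilirubin. A change in the microglia-like cells alone is argued against by the synaptic and neuronal list, whose median effect in endothelial-like cells differed by 0.139 (SD 0.527 over 19 genes) from that in microglia-like cells. The split of the libraries by mitochondrial percentage is argued against as the whole cause by the median of that list, -2.67 (SD 0.613) with a term for the split. Free RNA from other cells stays open: the 19 genes of the list had log2 fold changes below 0 in the whole libraries too, mostly nearer to 0, with a median log2 difference of -0.567 (SD 0.333), and a difference under 1 was what this explanation allowed. Whether less neuronal RNA was released at dissociation or bilirubin changed the neurons was not tested.

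Cebpb was lower in microglia-like cells of the knockout libraries. Free RNA from other cells, assumed to add at most the whole-library CPM, is argued against by the log2 ratio left after that CPM was taken off, -3.03 (error 0.429). The split by mitochondrial percentage is argued against by -2.88 (SE 0.341) with its term. A wide deletion that lowers the genes around Cebpb is argued against by the 9 measured genes within 500 kb, with a median of -0.158 (SD 0.506). A smaller deletion or a variant need not move that median. Such a change at Cebpb, a batch shared by the knockout libraries and an effect of the knockout stay open, as untested. These values hold for microglia-like cells; in endothelial-like and choroid plexus-like cells Cebpb lay below its whole-library level in WT bilirubin (63.7 and 28.1 against 86.7 CPM).

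Lcn2, Lrg1 and Scgb3a1 were higher in endothelial-like cells of the WT bilirubin libraries. Free RNA from other cells, if at the whole-library level, is argued against by the WT bilirubin levels in endothelial-like cells. These were 172, 61.8 and 456 CPM, against 92, 12.7 and 26.6 in the whole libraries. After the whole-library CPM was taken off, the median log2 ratio of the 3 genes was 4.92 (SD 1.12 over the genes). Lcn2 and Lrg1 swell this ratio, since their vehicle levels lay near the whole-library ones (10.3 against 8.58 and 2.57 against 2.1 CPM). Free RNA itself was not measured. The split by mitochondrial percentage is argued against by a median of 4.51 (SD 0.641) with its term. A larger share of venous cells cannot be told apart from a rise within cells. The other venous genes Vwf, Ackr1, Slc38a5 and Nr2f2 had a median of 1.53 with an SD of 0.88, too wide a spread to decide. Vwf (1.35), Ackr1 (2.3) and Slc38a5 (1.71) rose by edgeR (adjusted p = 0.0314, 0.0162 and 0.0114). Nr2f2 did not pass (0.206, adjusted p = 0.867). Whether the share of venous cells has a part in the falls in the knockout was not tested. An effect of bilirubin on the endothelial-like cells stays open, as untested.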

How the results depend on the processing

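The mitochondrial term, the genes above their whole-library level, the largest cluster of the class alone, the crossed pairing and, for the correlation, each library left out were chosen only after the data were seen. The causes of the changes below were not tested unless given. For the knockout against vehicle, the mitochondrial term is set only by the difference between the WT bilirubin libraries, so its count there is no separate check. Where a library left out leaves 1 in its group, that library is assumed to vary like the others. What depth limits was not tested; in simulated microglia-like cells 2-fold changes were found for 5% and 3% of genes. All alternatives chosen before the data were seen were run; the correlation has no value with only the 4 libraries compared.

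For bilirubin against vehicle in microglia-like cells (234 genes, 15 higher and 219 lower), the count was 358 with DESeq2, 2 with RLE size factors (2 higher, 0 lower), 927 with no low-count filter, 1395 with the mitochondrial term, 2 with the stricter cell filter, 880 at Leiden resolution 2, 38 with an equal number of cells, 3 in the largest cluster, 0 with only the 4 libraries compared, and 1 among genes above their whole-library level. It ran from 0 to 1454 with 1 library left out. For the knockout against WT bilirubin (1 gene), it was 3 with DESeq2, 13 with no filter, 2 with an equal number of cells and 5 with 4 libraries, and ran from 0 to 61. For the knockout against vehicle (0 genes), it was 3 with DESeq2, 103 with no filter, 469 with the mitochondrial term, 2 at resolution 2 and 2 with 4 libraries, and ran from 0 to 230.

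The samples share only a replicate number. With a replicate block the counts were 638, 1 and 1 in the same order, 1424 and 20 in the other classes, and 14 and 11 lists. Named bilirubin calls lost under it were Socs3 in microglia-like, Bc1 in mural-like, Mog in oligodendrocyte-like, and Ptgds, Basp1 and Cck in fibroblast-like cells. Named knockout calls lost under it were Ptgds, S100a6 and H1f4 in fibroblast-like and S100a9 in ependymal-like cells. The deviations of libraries with the same number correlated at -0.0944, -0.0825 and -0.107. With the crossed pairing, the knockout against vehicle called 0.

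Over the other classes (1069 calls for bilirubin), the count was 447 with DESeq2, 1838 with no filter, 2499 with the mitochondrial term, 477 with an equal number of cells, 551 in the largest clusters and 27 among genes above their whole-library level, where fewer genes are tested. It ran from 119 to 2910 with 1 library left out. For the knockout (18 calls) it was 91 with no filter, 58 with the mitochondrial term, 29 with 4 libraries and 10 above the whole-library level, and ran from 18 to 461.

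The number of lists called for bilirubin (15) was 0 with an estimated correlation and 0 by fry, and ran from 14 to 18. For the knockout (11) it was 3 with the mitochondrial term, 0 with an estimated correlation and 0 by fry, and ran from 4 to 20. The mitochondrially encoded list turned lower with bilirubin under the mitochondrial term (adjusted p = 0.0371) and without WT bilirubin replicate 1; with 1 library left out its adjusted p ran from 2.59e-28 to 0.0285. In the knockout comparison it turned lower under that term (adjusted p = 0.195) and without WT bilirubin replicate 2, with adjusted p from 2.38e-35 to 0.226.

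The correlation across genes (-0.547) went to 0.05995, the opposite sign, with the mitochondrial term, and ran from -0.8603 to -0.2729 with 1 library left out. With that term the bilirubin comparison rests on WT bilirubin replicate 2 and the knockout comparison on replicate 1, so they share no library, and the value of -0.487 simulated for unchanged groups does not apply to it. The log2 fold change of Trpm2 ran from -1.15 to -0.1512 and kept its sign in every setting. The number of classes with a changed share stayed 0. Of the values of named genes under alternatives, 2874 kept their direction and side of the threshold, 390 lost a call, 139 gained one, 26 without a call changed sign, and 0 reversed. Of the called lists, 170 values kept both and 86 lost the call; of the counts in single classes 138 stayed within 1.5 times, 99 were higher and 87 lower.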
